A study of Homo sapiens with 15 samples.

How the data were processed

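RNA sequencing had been done on LNCaP cells, an established androgen-sensitive human prostate cancer line, grown in RPMI medium with serum. The cells had been infected for 4-5 days with lentiviruses carrying a control vector (pLKO) or a short hairpin RNA against PALI1, G9a, JARID2 or SUZ12. These 5 groups, named pLKO, shPALI1, shG9a, shJarid2 and shsuz12, had 3 libraries each, 15 in all. Total RNA was isolated with the nucleospin RNA kit and libraries were made with the NEBNext Ultra kit, per the labels.

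The authors deposited 1 table of RPKM values, that is, reads scaled to the length of the gene model and to the size of the library, with 1 column per library. Per the submitters' processing notes, reads were aligned with STAR to hg38; the version of STAR, the counter and the gene annotation are not given in the sources used here. The table had 26475 gene names, of which 26443 carried values and 32 were names alone. A further check found 28 names turned into dates by spreadsheet software and 2 names that stood on 2 lines each; the mitochondrially encoded mRNAs were represented by 0 of 13 genes. Column sums lay between 250161 and 318754, so the values were not rescaled to a common sum.

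Sequencing depth was worked out from the values themselves. For genes with few reads, RPKM moves in steps of 1 read, and the size of the step in short RNA genes gave 10.56 to 19.36 M reads per library. With these totals, 92.8% to 94.7% of the values of short RNA genes under 50 reads were within 0.05 of a whole number of reads. The genes at 1 read that gave the step are among them, so this check is in part circular. At these depths, 1 RPKM in a gene of 2 kb stood for 21.1 to 38.7 reads.

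Differences between groups were tested with limma 3.58.1 in R 4.3.3, with a two-sided moderated test, a mean-variance trend and 1 model over the 15 libraries with group as its term. The values were log2(RPKM + 1), and genes with an RPKM of at least 1 in at least 3 libraries were kept, which left 12715 genes. On this scale a fold change is smaller than the ratio of RPKM values, mostly so for genes with low values. Adjusted p values are Benjamini-Hochberg values within a comparison, and a gene passed at 0.05. Each knockdown was compared with pLKO, and shPALI1 was compared with shG9a, shsuz12 and shJarid2, and shsuz12 with shJarid2, in contrasts that do not use pLKO. Genes were counted as not overlapping when the 3 libraries of one group lay beyond the 3 of the other, which chance gives for 10% of genes. The p values measure the spread between these libraries, which may be technical, since the labels do not say whether the replicates came from separate cultures.

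The grouping, the tests, the gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule names the targeted genes in every group and, in each comparison with pLKO, the 7 largest rises and the 7 largest falls. These were taken among genes that passed, did not overlap between groups and had a mean RPKM of at least 2 in the higher group. Names of clones, loci and pseudogenes were skipped, and some genes that the rule names are not reported here. It also names 4 genes each way per contrast of 2 knockdowns, 6 each way for genes shared between knockdowns, and the 4 members of each list with the smallest p. Gene locations and 3′ UTR sequences were read from GENCODE v29 on GRCh38. Gene lists with at least 3 tested members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry.

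The procedure was tested on simulated data built from the table. In the shPALI1 comparison, 71 of 100 genes changed by 1.5-fold and 92 of 100 genes changed 2-fold were recovered, with 7 false calls among the other genes and 0 calls in an unchanged comparison run in limma. The list test recovered 1 of 1 planted list and called 0 of 20 random lists. Simulated genes varied independently of each other. These runs therefore do not show how often lists of correlated genes, or genes that vary together, are called falsely. A search for 7-base words in 3′ UTRs, described with its results, recovered 2 of 2 planted words. Overlaps between knockdowns that share the pLKO libraries were set beside 20 simulated draws of unchanged groups.

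Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter on a mean RPKM of at least 3, median ratio scaling, quantile normalization, and rescaling to a common sum (TPM). Others were a model over the 6 libraries of a comparison alone, array weights, and the replicate number as a term. Each library was also left out in turn. The estimation of array weights stopped before it converged. A correction of each library for transcript length and GC content, a test without genes that hold the word found for a knockdown, and the leaving out of libraries in the list tests were added after seeing the data. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and plots with matplotlib 3.10.9.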

Results

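Gene expression was measured by RNA sequencing in 15 libraries of LNCaP cells, 3 for each of 5 groups. One group carried the control vector pLKO, and the others carried a hairpin against PALI1, G9a, JARID2 or SUZ12. Depth was 12.36, 15.93 and 11.65 M reads in the pLKO libraries and 10.56, 13.75 and 13.73 M in shPALI1. It was 13.62, 15.2 and 14.33 M in shG9a, 15.83, 14.71 and 12.45 M in shJarid2, and 19.36, 13.52 and 12.04 M in shsuz12. Within pLKO, shPALI1, shG9a and shsuz12, the log2(RPKM + 1) values of pairs of replicates correlated across genes with r between 0.986 and 0.992. In shJarid2, replicate 3 correlated with the others at 0.975 and 0.978, against 0.992 between replicates 1 and 2. These r describe genes, which are not independent replicates.

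SUZ12 and JARID2 are subunits of PRC2, the complex that methylates lysine 27 of histone H3, and PALI1 is a PRC2 accessory protein made from the LCOR locus. G9a, encoded by EHMT2, methylates lysine 9 of histone H3. The series title links PALI1 to PRC2 and to chromatin bound by G9a, so the comparisons ask which genes respond to loss of each factor and which respond to several.

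The targeted genes were measured in every group. The LCOR gene lies on chromosome 10 from 96832282 to 96995959 on the plus strand of GRCh38, and the table lists C10orf12, the part that distinguishes PALI1, apart from LCOR. C10orf12 was at 0.964 ± 0.27 RPKM (SD, n = 3) in shPALI1 and 4.05 ± 0.35 in pLKO, which is 23.8% of the control level (log2 change -1.37 ± 0.21 SE, adjusted p = 0.00013). The LCOR row was at 3.09 ± 0.28 against 5.15 ± 0.82 RPKM, or 60% (adjusted p = 0.0067). Since PALI1 is made from the same locus and the gene annotation is not given, the LCOR row may also count reads of PALI1 transcripts. Whether LCOR itself fell is therefore open. Effects of lower PALI1 and of any fall in LCOR cannot be told apart in shPALI1. EHMT2, on chromosome 6 from 31879759 to 31897687 on the minus strand, fell to 25.7% under shG9a (0.955 ± 0.028 against 3.72 ± 0.39 RPKM, log2 change -1.27, adjusted p = 2.1e-08). JARID2, on chromosome 6 from 15246296 to 15522040 on the plus strand, fell to 18.3% under shJarid2 (1.58 ± 0.23 against 8.62 ± 0.39 RPKM, log2 change -1.90, adjusted p = 7.5e-10). SUZ12, on chromosome 17 from 31937018 to 32001045 on the plus strand, fell to 12.5% under shsuz12 (2.53 ± 0.22 against 20.2 ± 2.1 RPKM, log2 change -2.58, adjusted p = 7.1e-10).

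Some targeted genes also moved under other hairpins. Under shsuz12, LCOR rose to 158% of pLKO (8.12 ± 0.65 RPKM, adjusted p = 0.0051) and JARID2 rose to 141% (12.2 ± 0.46 RPKM, adjusted p = 0.00022). EHMT2 fell to 71.5% under shJarid2 (adjusted p = 0.00099) and was at 80.3% under shsuz12 (adjusted p = 0.015). The EHMT2 call in shsuz12 was lost without pLKO replicate 1 (adjusted p = 0.0742), with median ratio scaling (0.121) and with TPM (0.164). C10orf12 was at 69.9% in shJarid2, where its libraries read 3.976, 3.157 and 1.361 RPKM, and did not pass (adjusted p = 0.077), but passed without shJarid2 replicate 1. LCOR in shJarid2, at 77.2%, did not pass but passed without pLKO replicate 1 or without shJarid2 replicate 2. JARID2 in shPALI1, at 86.4%, did not pass (adjusted p = 0.063) but passed without shPALI1 replicate 3. SUZ12 did not pass in shPALI1, at 82.9% (adjusted p = 0.065), but passed with array weights (0.00669), with the length and GC correction (0.00301) and in a model of the 6 libraries alone (0.0444). Array weights also let C10orf12 pass in shJarid2 (0.0315) and in shsuz12 (0.0274, at 77%) and LCOR in shG9a (0.0214, at 82.4%). The estimation of these weights stopped before it converged, which limits each call made with them, that of SUZ12 included. The model of the 6 libraries also let C10orf12 pass in shsuz12. The length and GC correction also let LCOR pass in shG9a (0.0249) and EHMT2 in shPALI1 (0.00424, at 107%).

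**Figure D1:**
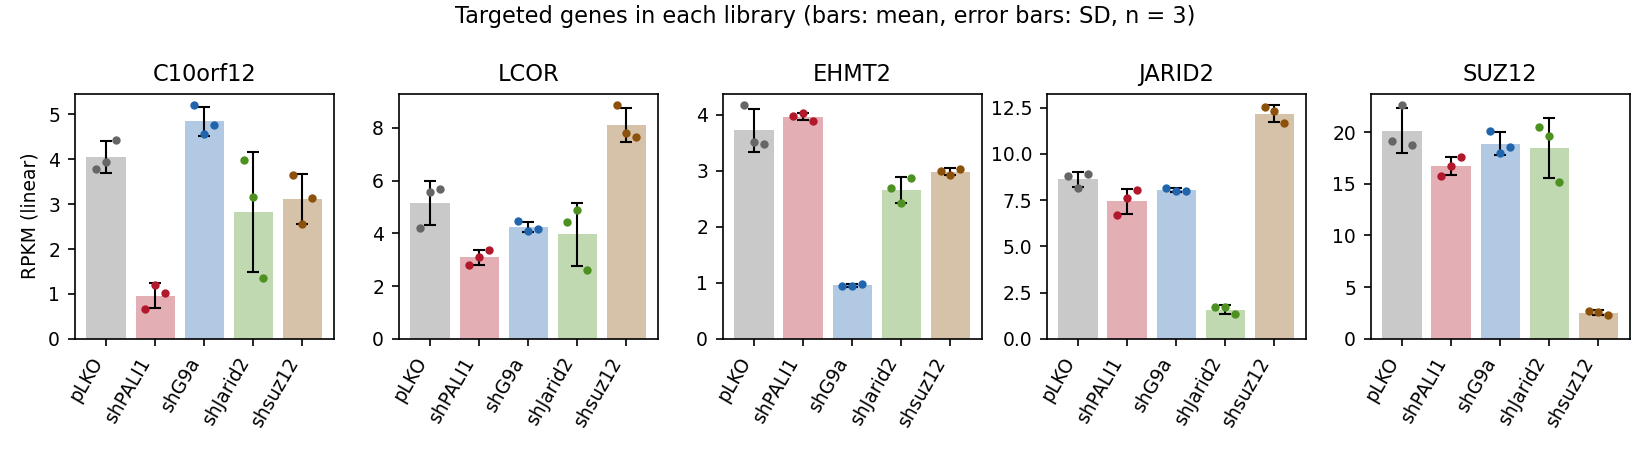
RPKM of C10orf12, LCOR, EHMT2, JARID2 and SUZ12 in the 5 groups on linear axes; points are libraries, bars are means and error bars are SD (n = 3). Each gene was lowest in the group whose hairpin targets it, with C10orf12 at 23.8%, EHMT2 at 25.7%, JARID2 at 18.3% and SUZ12 at 12.5% of pLKO.

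The shPALI1 comparison asked which genes change under the hairpin against PALI1, where the LCOR row fell as well. Androgen receptor targets fell under shPALI1: of 26 tested genes that the receptor is known to activate, 21 fell and 2 rose (22 and 3 when adjusted over the list alone), with a median log2 change of -1.09 (camera adjusted p = 2.5e-09, adjusted p = 0.014 with an estimated correlation). Among them TMPRSS2, a membrane protease gene under direct androgen control, fell by 1.78 and CENPN fell by 1.69. Genes of the actin cytoskeleton were among the largest rises. ACTA2, which encodes smooth muscle actin, rose from 1.6 ± 0.05 to 15.4 ± 1.5 RPKM, and PALLD, which encodes an actin-binding scaffold, rose from 4.53 ± 0.23 to 32.4 ± 3.3 RPKM (SD, n = 3). SCD, the desaturase that makes monounsaturated fatty acids, fell from 160 ± 7.2 to 28.6 ± 4.4 RPKM.

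With limma, 2101 genes rose and 3189 fell under shPALI1, 41.6% of those tested. Of these, 211 rose and 229 fell at least 2-fold, and the median change over all genes was -0.052. The excess of falls depended on the scaling, with 2643 higher and 2679 lower under median ratio scaling, 2787 and 2887 under quantile normalization and 3119 and 3261 with the length and GC correction, while TPM kept it (2128 and 2958). The groups did not overlap for 54.5% of genes, where chance gives 10%. The log2 rise was 2.84 ± 0.08 (SE) for CTGF, a matrix-associated gene (0.0327 to 6.38 ± 0.45 RPKM, adjusted p = 6.1e-11), 2.67 ± 0.11 for the matrix protease gene MMP10 and 2.58 ± 0.12 for FSCN1, which encodes the actin-bundling protein fascin. KHDC1L rose by 2.84 ± 0.19 and PRAMEF12, on chromosome 1 from 12774841 to 12777906, rose by 2.56 ± 0.12; both belong to families with near-identical copies, so the reads may be shared between members. Among falls, ACPP, which encodes prostatic acid phosphatase, changed by -2.41 ± 0.07 (12.2 ± 0.78 to 1.48 ± 0.013 RPKM). The water channel gene AQP3 changed by -2.09, the ceramide desaturase gene DEGS1 by -2.08, SERINC5 by -1.98 and PSD4 by -1.94.

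Further lists passed in shPALI1. The clustered protocadherins beta, adhesion genes with similar copies, all rose, 8 of 8 tested (median 1.12, adjusted p = 2.1e-08, 0.0042 with an estimated correlation), with PCDHB5 at 1.42 and PCDHB15 at 1.20. Cholesterol synthesis genes fell in 16 of 19 cases and rose in 0 (17 and 0 adjusted over the list alone), with a median of -0.47 (adjusted p = 5.6e-07, 0.014 with an estimated correlation). SQLE changed by -1.29, INSIG1 by -1.13, MSMO1 by -1.09 and SREBF2, which encodes the regulator of this pathway, by -0.63. Interferon-stimulated genes rose, 9 of 16 against 1 that fell (10 and 1 adjusted over the list alone), with a median of 0.32 (adjusted p = 0.00049, 0.021 with an estimated correlation), among them IFIT1 at 1.00, DDX58 at 1.02 and IFI44 at 1.09. These lists and the androgen receptor list were the ones that held with an estimated correlation.

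Lists that passed with the preset correlation alone in shPALI1 were of cell cycle, lineage and stress genes. DNA replication genes fell, 14 of 22 with 0 rising (15 and 1 adjusted over the list alone), at adjusted p = 7e-04, and adjusted p = 0.38 with an estimated correlation, with CDC45 at -0.73 and E2F1 at -0.78. Mitotic genes fell, 10 of 20 (adjusted p = 0.0051, 0.39 with an estimated correlation), with CDC20 at -0.66 and AURKA at -0.56. p53 target genes rose, 12 against 5 of 22 (adjusted p = 0.011, 0.21 with an estimated correlation), with FAS at 1.22 and MDM2 at 0.87, while GDF15 fell by 1.11. Luminal prostate markers fell, 8 against 1 of 13 (adjusted p = 0.015, 0.12 with an estimated correlation), with KRT19 at -1.60 and HOXB13 at -1.02. Targets of the amino acid stress factor ATF4 rose, 9 against 4 of 21 (adjusted p = 0.019, 0.43 with an estimated correlation), a call lost without pLKO replicate 3 (0.0647). ATF3 rose by 1.83 and ASNS by 0.47. HOX genes, of which 10 of 39 were tested, fell in 6 cases and rose in 1 (adjusted p = 0.026, 0.21 with an estimated correlation), with HOXC4 at -0.85.

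The other lists did not pass in shPALI1. Germline genes, with 5 of 11 higher, had adjusted p = 0.065 and passed without shPALI1 replicate 3 (0.0318). Mesenchymal genes had 3 higher and 2 lower of 8 (adjusted p = 0.24), with VIM at 1.79 and TWIST1 at -0.69, and the unfolded protein response had 1 and 5 of 15 (0.24). MHC class I genes had 3 higher and 1 lower of 10 (4 and 2 adjusted over the list alone; 0.11). Genes reported as silenced by EZH2 had 1 and 1 of 9 (0.76), and other developmental transcription factors 4 and 2 of 19 (0.24), with ZIC2 at 1.41 and SOX9 at -1.20. PRC2 subunits, LCOR and C10orf12 included, had 3 and 3 of 15 (4 and 6 adjusted over the list alone; 0.76), H3K9 methylation genes 2 and 1 of 13 (0.29), hypoxia genes 3 and 7 of 18 (3 and 8 adjusted over the list alone; 0.51), imprinted genes 2 and 2 of 9 (0.81) and replication-dependent histones 1 and 4 of 12 (0.74). Basal markers had 0 higher and 2 lower of 4 (0 and 3 adjusted over the list alone; 0.28), and neuroendocrine markers 0 and 0 of 4 (1 and 2 adjusted over the list alone; 0.96). For the PRC2, developmental, EZH2-silenced and imprinted lists, the median and mean of the members, or the direction of the test, differed in sign. Of markers of other cell types, 1 immune gene, 1 endothelial gene and 2 fibroblast genes could be tested. Of the fibroblast genes, COL3A1 rose by 1.24 and COL1A1 fell by 0.41 (adjusted p = 0.0039), a call lost with the length and GC correction. The endothelial gene VWF fell by 0.28 (adjusted p = 0.02), a call lost with that correction, with the 6 libraries alone, without pLKO replicate 2 and without shPALI1 replicate 2. The immune gene CD68 rose by 0.46 (adjusted p = 0.011), a call lost without pLKO replicate 2.

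The 3′ UTRs of falling genes were searched for shared 7-base words after the calls had been seen. In shPALI1 the word GAGGATA was present in 10.7% of the 2965 genes that fell and had an annotated 3′ UTR. It was present in 6.2% of genes that did not fall and in 5.3% of genes that rose. SCD, PSD4, SQLE and SREBF2 hold it. The response of such genes to the hairpin and to the loss of PALI1 is confounded, since each target had 1 hairpin name.

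The shG9a comparison asked which genes change when the H3K9 methyltransferase is lowered. C2orf54 rose from 0.228 ± 0.12 to 69.3 ± 3.7 RPKM (SD, n = 3; log2 change 5.84 ± 0.15 SE, adjusted p = 2.3e-11), more than any other gene that met the naming rule. Cholesterol synthesis genes, which fell under shPALI1, rose under shG9a: 12 of 19 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 2.7e-08, 0.019 with an estimated correlation). FDFT1, which encodes squalene synthase, rose by 1.17 and SQLE, which encodes the enzyme of the next step, by 0.80. p53 target genes fell, 18 of 22 against 1 that rose, with a median of -0.71 (adjusted p = 2.4e-07, 0.023 with an estimated correlation). SESN1 changed by -2.03, ZMAT3 by -1.95, DDB2 by -1.19 and BTG2, an antiproliferative gene, by -0.89.

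Under shG9a, limma called 2338 genes higher and 3139 lower, 43.1% of those tested, with 193 and 235 of them changed at least 2-fold. With TPM, whose median change lay 0.102 above that of the RPKM, the split was 3126 and 2278. It was 2847 and 2722 with median ratio scaling, 2930 and 2917 with quantile normalization and 3286 and 3431 with the length and GC correction. The groups did not overlap for 58.3% of genes, where chance gives 10%. DIO3, which encodes an enzyme that inactivates thyroid hormone, rose by 2.80 ± 0.12 and the proteoglycan gene SDC4 by 2.76 ± 0.09 (10.3 ± 0.78 to 75.4 ± 4.7 RPKM). The androgen-conjugating enzyme gene UGT2B15 rose by 2.65 ± 0.1, the lipid transporter gene ABCA12 by 2.63 and the chaperone gene CLU by 2.41 ± 0.15. UGT2B15 has near-identical neighbours, so its reads may be shared. PPP3CA, the catalytic subunit of calcineurin, changed by -2.36 ± 0.08 (183 ± 16 to 34.6 ± 0.21 RPKM). The zinc transporter gene SLC30A4 changed by -2.21 ± 0.23, the adrenergic receptor gene ADRA2A by -2.21 ± 0.07, CREBL2 by -2.06, the Notch ligand gene JAG1 by -1.97 and the glutamate dehydrogenase gene GLUD1 by -1.97.

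Mitotic and replication genes passed in shG9a with the preset correlation alone. Mitotic genes fell, 17 of 20 (18 adjusted over the list alone), at adjusted p = 2.8e-06, and adjusted p = 0.37 with an estimated correlation, with BIRC5 at -1.48 and CDC20 at -1.01. Replication genes fell, 14 against 1 of 22 (15 and 1 adjusted over the list alone), at adjusted p = 0.00091, and 0.49 with an estimated correlation, with TYMS at -1.44. Androgen receptor targets did not pass, with 8 higher and 13 lower of 26 (9 and 14 adjusted over the list alone) and adjusted p = 0.17; CENPN changed by -1.07 and PPAP2A by -1.30. The unfolded protein response had 8 higher and 1 lower of 15 (adjusted p = 0.072). It passed without shG9a replicate 1 (0.0149), with median ratio scaling (0.0426), with the length and GC correction (0.0169) and without word carriers (0.0298). ATF4 targets had 2 higher and 9 lower (2 and 10 adjusted over the list alone; adjusted p = 0.091) and passed without pLKO replicate 3 (0.0305) and without word carriers (0.0197); PSAT1 fell by 1.31. MHC class I genes had 4 higher and 0 lower (0.098) and passed without shG9a replicate 1 (0.0466), with TAPBP at 1.24 and NLRC5 at 1.22. Other developmental factors had 1 and 8 (1 and 9 adjusted over the list alone; 0.098) and passed without pLKO replicate 3 (0.0494).

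The remaining lists did not pass in shG9a. EZH2-silenced genes had 5 higher and 2 lower (adjusted p = 0.098), with MSMB at 2.23 and CDKN2A at -1.20. The protocadherins had 3 and 0 (0.098), histones 0 and 5 (0.098), and germline genes 5 and 2 (0.17), with MAGEC2 at 1.56. PRC2 subunits had 1 and 6 (0.24), with AEBP2 at -0.71, H3K9 methylation genes 3 and 5, the target EHMT2 included (0.37), and luminal markers 5 and 3 (0.36), with CLDN4 at 1.34. Imprinted genes had 4 and 2 (0.35), interferon-stimulated genes 2 and 3 (1 and 2 adjusted over the list alone; 0.75), HOX genes 1 and 2 (0.75), mesenchymal genes 3 and 4 (0.75), basal markers 1 and 2 (0.75), neuroendocrine markers 1 and 1 (2 and 2 adjusted over the list alone; 0.75) and hypoxia genes 6 and 7 (0.99). In the mesenchymal, basal and hypoxia lists the median, the mean or the test differed in sign. Of the markers of other cell types, VWF rose by 0.88 (adjusted p = 2.8e-06) and COL3A1 by 0.33 (0.011), and CD68 and COL1A1 did not pass. The word TTTAACA was present in 29.1% of the 2871 falling genes with a 3′ UTR, in 17.6% of genes that did not fall and in 13.3% of rising genes; PPP3CA, CREBL2, GLUD1, ZMAT3, BIRC5 and AEBP2 hold it.

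The shJarid2 comparison asked which genes change when this PRC2 subunit is lowered. Mitotic genes fell under shJarid2, 20 of 20 tested, with a median of -0.98 (camera adjusted p = 4.3e-11). With an estimated correlation the list did not pass (adjusted p = 0.13). CCNA2, a cyclin gene, changed by -1.89, CDC20 by -1.85, the kinase gene PLK1 by -1.52 and CCNB1 by -1.12. PLA2G2A, which encodes a secreted phospholipase, rose from 15.9 ± 3.1 to 347 ± 97 RPKM (SD, n = 3; log2 change 4.35 ± 0.17 SE, adjusted p = 6.9e-10). TRPM8, an androgen-regulated ion channel gene, rose from 5.85 ± 0.49 to 69.8 ± 8.8 RPKM.

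Under shJarid2, limma called 3024 genes higher and 3462 lower, 51% of those tested, with 391 and 337 changed at least 2-fold. Without shJarid2 replicate 3, which stood apart from the other two, 3198 were higher and 3775 lower. The groups did not overlap for 51.2% of genes, where chance gives 10%. CAMK2N1, an inhibitor of a calcium-dependent kinase, rose by 3.33 ± 0.11 (32.7 ± 4.5 to 338 ± 43 RPKM), PLA2G2F by 3.27, the dynein light chain gene DYNLRB1 by 2.63 ± 0.12, the keratin gene KRT19 by 2.62 ± 0.15 and THRSP by 2.59. ATP1B1, a subunit of the sodium pump, changed by -2.66 ± 0.07 (354 ± 21 to 55.1 ± 4.3 RPKM). The lamin gene LMNB1 changed by -2.24, AK4 by -2.24, the deubiquitinase gene USP22 by -2.14, TOMM5 by -2.12, the DNA glycosylase gene TDG by -2.11 and the transferrin receptor gene TFRC by -2.10 (102 ± 5.5 to 23.1 ± 3.7 RPKM). The word TGGTGTA was present in 16.3% of the 3020 falling genes with a 3′ UTR, in 7.3% of genes that did not fall and in 5.5% of rising genes. LMNB1, AK4, USP22, TOMM5, TDG and CCNA2 hold it. Among list members named below, the falling genes CBX1, MTHFD2 and INSIG1 and the rising gene NUPR1 hold it as well.

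Other lists that passed in shJarid2 did so with the preset correlation alone. Replication genes fell, 21 of 22 (median -0.59, adjusted p = 1.8e-08, 0.2 with an estimated correlation), with TYMS at -1.06 and MCM7 at -0.92. Luminal markers rose, 10 against 2 of 13 (adjusted p = 0.0068, 0.13 with an estimated correlation), with CLDN4 at 1.30 and KRT18 at 0.80. p53 target genes fell, 14 against 3 of 22 (adjusted p = 0.014, 0.28 with an estimated correlation), with PLK3 at -1.55 and AEN at -0.80. Androgen receptor targets had 8 higher and 10 lower (9 and 11 adjusted over the list alone; adjusted p = 0.96), with TMPRSS2 at -0.59. PRC2 subunits, with the target JARID2 among them, had 1 higher and 5 lower (adjusted p = 0.13) and passed without word carriers (0.0293), a set that still held JARID2; MTF2 changed by -0.59 and EZH2, the catalytic subunit, by -0.53. H3K9 methylation genes had 1 and 6 (0.23), with CBX1 at -1.72, and mesenchymal genes 4 and 1 (0.19), with THBS1 at 1.69 and TAGLN at 1.34.

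The remaining lists did not pass in shJarid2. HOX genes had 4 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.27), with HOXC6 at 0.62. MHC class I genes had 3 and 1 (0.27), with TAPBP at 1.20, protocadherins 0 and 2 (0.27), with PCDHB2 at -0.74, interferon-stimulated genes 2 and 6 (0.3), and hypoxia genes 7 and 3 (0.4). Cholesterol synthesis genes split, 5 higher and 5 lower (0.78), with INSIG1, which holds the word, at -2.01. ATF4 targets had 8 and 6 (0.55), with NUPR1 at 1.65 and MTHFD2 at -1.22, germline genes 4 and 0 (0.46), neuroendocrine markers 0 and 2 (0.52) and histones 3 and 1 (0.56). Basal markers had 1 and 2 (0.8), with KRT14 at 1.89, imprinted genes 1 and 2 (0.96), the unfolded protein response 5 and 5, EZH2-silenced genes 3 and 4, and developmental factors 5 and 4 (4 and 4 adjusted over the list alone), each of these last with adjusted p near 1. Of the markers of other cell types, COL1A1 fell by 1.20 (adjusted p = 2.5e-07) and COL3A1 rose by 0.39 (0.0031). CD68 rose by 0.45 (0.011), a call lost without pLKO replicate 2 (0.0597) and with the 6 libraries alone (0.0518). VWF rose by 0.27 (0.02), a call lost without pLKO replicate 3 (0.0858), without shJarid2 replicate 2 (0.0964) and with the 6 libraries alone (0.0937). In the EZH2-silenced, basal, unfolded protein, cholesterol and germline lists the median, the mean or the test differed in sign.

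The shsuz12 comparison asked which genes change when a core PRC2 subunit is lowered. Mitotic and replication genes fell under shsuz12, 20 of 20 mitotic genes (median -1.25, camera adjusted p = 9.8e-12) and 22 of 22 replication genes (median -0.98, adjusted p = 3e-11). Both had adjusted p = 0.14 with an estimated correlation. CDC20 changed by -1.86, PLK1 by -1.51, CDC45 by -1.62, TYMS by -1.61 and MCM4, a helicase subunit gene, by -1.22. SI, which encodes the intestinal enzyme sucrase-isomaltase, rose from 0.831 ± 0.14 to 42.4 ± 1 RPKM (SD, n = 3; log2 change 4.57 ± 0.11 SE, adjusted p = 8.5e-12). S100P, a calcium-binding protein gene, fell from 18.7 ± 3 to 0.996 ± 0.17 RPKM (-3.30 ± 0.18, adjusted p = 6.7e-09).

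Under shsuz12, limma called 2683 genes higher and 4171 lower, 53.9% of those tested, with 276 and 408 changed at least 2-fold. The direction of the split depended on the scaling. Median ratio scaling gave 3612 higher and 3104 lower and TPM gave 3413 and 3026, with median changes 0.108 and 0.114 above that of the RPKM. Quantile normalization gave 3431 and 3558 and the length and GC correction 3704 and 3945. Without the genes that hold the word given for shsuz12, 2750 genes were lower. The groups did not overlap for 63.1% of genes, where chance gives 10%. CBLN2, a synapse organizer gene, rose by 3.04 ± 0.11, TENM1 by 2.80, the nicotinic receptor gene CHRNA2 by 2.75 ± 0.1 (1.61 ± 0.24 to 16.5 ± 0.95 RPKM), PLA2G2A by 2.46 ± 0.17, the glutamate receptor gene GRIN3A by 2.40 and LRRN1 by 2.39. The lysine methyltransferase gene SETD7 changed by -2.21, BZW1 by -2.16, the kinase gene NEK7 by -2.09, the serine transporter gene SFXN1 by -2.05 and TFRC by -2.03. The word AAATGAA was present in 36.5% of the 3845 falling genes with a 3′ UTR, in 27.8% of genes that did not fall and in 24.0% of rising genes. It is held by SETD7, BZW1, NEK7, SFXN1 and TFRC, and by the rising genes CBLN2, TENM1 and GRIN3A. Among falling list members named below, PSAT1, INSIG1, ELL2, TMPRSS2, FN1 and SUV39H1 hold it as well.

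Other lists passed in shsuz12 with the preset correlation alone. ATF4 targets fell, 17 against 2 of 21 (median -0.69, adjusted p = 0.00039, 0.3 with an estimated correlation), with PSAT1 at -1.39, XPOT at -1.11 and ASNS at -1.01. p53 target genes rose, 11 against 3 of 22 (adjusted p = 0.0067, 0.2 with an estimated correlation, 0.055 without word carriers), with TP53I3 at 2.12 and FAS, a death receptor gene, at 1.34. Cholesterol synthesis genes rose, 9 against 3 of 19 (10 and 3 adjusted over the list alone; adjusted p = 0.011, 0.2 with an estimated correlation), with SC5D at 1.23, while INSIG1 fell by 1.15. Androgen receptor targets had 7 higher and 14 lower (adjusted p = 0.27); ELL2 fell by 1.68, TMPRSS2 fell by 1.17, and PTGER4 rose by 1.47. Interferon-stimulated genes had 1 higher and 11 lower (adjusted p = 0.064) and passed with median ratio scaling (0.0231), with IFIH1 at -0.79. PRC2 subunits had 3 and 7, the target SUZ12 included (0.33), with C17orf96 at -1.16 and EZH2 at -0.58, and protocadherins 4 and 0 (2 and 0 adjusted over the list alone; 0.084), with PCDHB2 at 1.16.

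The remaining lists did not pass in shsuz12. Germline genes had 6 higher and 3 lower (6 and 4 adjusted over the list alone; adjusted p = 0.18), with MAGEC2 at 1.78 and MAGEA4 at -0.96. Mesenchymal genes had 4 and 4 (0.52), with ACTA2 at 1.63 and FN1 at -1.24, neuroendocrine markers 1 and 0 (0.52), with SYP at 1.82, imprinted genes 4 and 2 (0.52), and MHC class I genes 1 and 2 (0.55). H3K9 methylation genes had 2 and 6 (0.68), with SUV39H1 at -0.91, and EZH2-silenced genes 2 and 3 (0.78), with TIMP2 at 1.40. HOX genes had 2 and 3, other developmental factors 3 and 4, luminal markers 4 and 5, basal markers 1 and 0, the unfolded protein response 4 and 5 (4 and 6 adjusted over the list alone), hypoxia genes 4 and 6 and histones 1 and 5, each with adjusted p = 0.86. In the HOX, developmental, luminal, basal, neuroendocrine, unfolded protein and hypoxia lists the median, the mean or the test differed in sign. CDH1, an adhesion gene in the luminal list, rose by 1.12. Of the markers of other cell types, CD68, VWF, COL1A1 and COL3A1 did not pass, but COL3A1 was lower and passed with a pseudocount of 0.1 (0.0212), quantile normalization (0.00765) and the length and GC correction (0.0437).

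**Figure D2:**
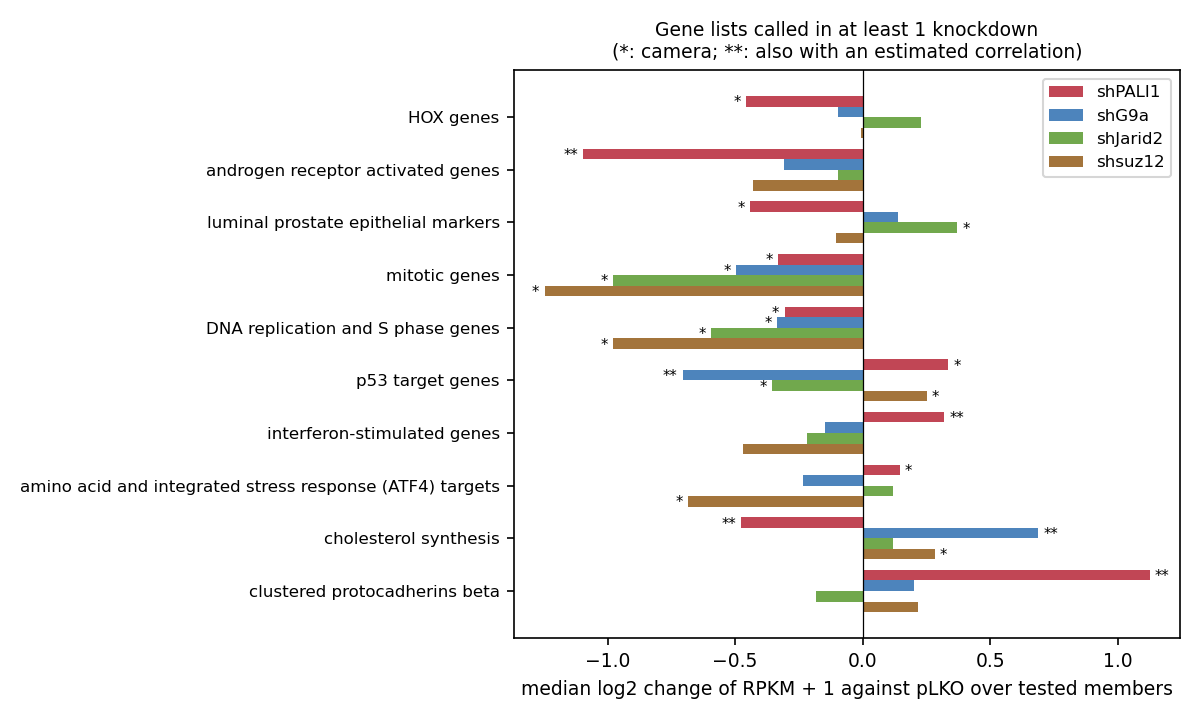
Median log2 change of RPKM + 1 against pLKO over the tested members of each list called in at least 1 knockdown, as bars by knockdown; 1 star marks a camera call and 2 stars a call that held with an estimated correlation. Cholesterol synthesis lies at -0.47 in shPALI1 and 0.69 in shG9a, and mitotic genes lie below 0 in each knockdown.

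The contrast of shPALI1 with shG9a asked where loss of the accessory subunit and loss of the H3K9 methyltransferase differ. It called 3066 genes higher and 3061 lower in shPALI1 (326 and 412 by at least 2-fold), or 2323 and 3722 with TPM, and the groups did not overlap for 63.6% of genes, where chance gives 10%. SCD was lower in shPALI1 by a log2 difference of -3.90 (28.6 ± 4.4 against 437 ± 16 RPKM, SD, n = 3, adjusted p = 1.7e-11). C2orf54 differed by -5.65 and SDC4 by -3.43. PRAMEF12 was higher in shPALI1 by 3.72, ADRA2A by 3.34 (35.4 ± 2.1 against 2.61 ± 0.081 RPKM), KHDC1L by 3.10 and CTGF by 2.87.

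The contrast of shPALI1 with shsuz12 asked where the accessory and the core PRC2 subunit differ. It called 3933 genes higher and 3180 lower in shPALI1 (414 and 494 by at least 2-fold). With TPM the split turned to 3024 and 3811 and with median ratio scaling to 3444 and 3686, and without the genes that hold a word 2485 were higher. The groups did not overlap for 66.5% of genes, where chance gives 10%. PRAMEF12 was higher in shPALI1 by 3.44, KHDC1L by 2.83 and CTGF by 2.75. SI was lower by -4.42, CHRNA2 by -3.66, ACPP by -3.36 and SCD by -2.93. RPPH1, the RNA of ribonuclease P, was higher by 2.75 ± 1.03 (30.2 ± 26 against 2.86 ± 2.4 RPKM, adjusted p = 0.036). Its call was lost without shPALI1 replicate 1 (0.0843) or 2 (0.142), without shsuz12 replicate 1 (0.0897) or 2 (0.102), and with no filter (0.0751).

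The contrasts with shJarid2 asked the same of the JARID2 subunit. shPALI1 against shJarid2 called 3874 genes higher and 4047 lower in shPALI1 (597 and 829 by at least 2-fold), or 4024 and 4118 without shJarid2 replicate 3, and the groups did not overlap for 62.5% of genes. This split turned to 4190 and 3826 with median ratio scaling, 4059 and 3833 with quantile normalization, 4104 and 3716 with TPM and 4546 and 4113 with the length and GC correction. PRAMEF12 was higher in shPALI1 by 3.58, UGT2B28 by 3.37, the tubulin gene TUBA1A by 3.33 and FSCN1 by 3.18. KRT19 was lower by -4.22, PLA2G2A by -4.11 and ACPP by -3.82. shsuz12 against shJarid2 called 3203 genes higher and 4296 lower in shsuz12 (492 and 610 by at least 2-fold), or 3316 and 4331 without shJarid2 replicate 3, and the groups did not overlap for 60.8%. Median ratio scaling turned this split to 3975 and 3515 and TPM to 4191 and 3130, and without the genes that hold a word 2832 were lower. SI was higher in shsuz12 by 3.55, the transthyretin gene TTR by 2.95, TP53I3 by 2.65 and TUBA1A by 2.60. S1PR3 was lower by -3.53, PLA2G2F by -3.11, NPPC by -3.09 and CD2AP by -3.02.

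Responses shared between knockdowns were compared next, to ask whether PALI1, G9a and PRC2 act on common genes. KLK3, which encodes prostate-specific antigen, fell under both shPALI1 and shG9a, to 300 ± 40 and 364 ± 22 RPKM from 1110 ± 65 in pLKO (SD, n = 3). Its neighbour KLK2 changed by -1.92 and -1.50, the zinc transporter gene SLC30A4 by -1.86 and -2.21, and ACPP by -2.41 and -1.34. BECN1, which changed by -1.35 and -1.54, holds both words, and KLK2 holds the shPALI1 word. CLU rose by 2.55 and 2.41 in the same pair, MMP10 by 2.67 and 2.21, C8orf4 by 2.52 and 1.47 and FSCN1 by 2.58 and 1.34. Under both shPALI1 and shsuz12, CBLN2 rose by 2.36 and 3.04, EPHA7 by 1.96 and 2.05 and ACTA2 by 2.65 and 1.63. S100P changed by -1.82 and -3.30 in this pair, NPPC by -1.93 and -1.72 and PHLDA2 by -1.48 and -1.48. DCP2, which holds both words, changed by -1.33 and -1.97, and NPPC and PHLDA2 hold the shsuz12 word.

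Of the genes called in shPALI1 and shG9a, 770 rose in both and 1317 fell in both, where 386.3 and 787.3 would be shared if the calls were independent, and 784 moved in opposite directions (1105 if independent). For shPALI1 and shsuz12, 865 rose and 1542 fell in both (443.3 and 1046 if independent), with 899 opposite (1362). For shPALI1 and shJarid2, 609 rose and 996 fell in both (499.7 and 868.3), with 1479 opposite (1330). Shared and opposite calls of this pair both lay above independence, so an excess over independence alone does not show a shared response. shG9a and shsuz12 shared 1288 rises and 1977 falls (493.3 and 1030), shG9a and shJarid2 1091 and 1347 (556 and 854.7), and shJarid2 and shsuz12 1159 and 1709 (638.1 and 1136). Without shJarid2 replicate 3 the pairs with shJarid2 shared 762 and 1347 genes with shPALI1, 1322 and 1770 with shG9a and 1332 and 2078 with shsuz12. The length and GC correction raised the shared rises of shPALI1 to 1325 with shG9a, 1475 with shsuz12 and 1022 with shJarid2. Array weights, whose estimation did not converge, raised the shared falls of shJarid2 to 1552 with shPALI1 and 2054 with shG9a. TPM lowered the shared falls of shG9a and shsuz12 to 1248. Without the genes that hold a word, the shared falls of shsuz12 were 1006 with shPALI1, 1178 with shG9a and 1046 with shJarid2, since fewer genes were tested. Of the 784 genes called in opposite directions in shPALI1 and shG9a, 273 were higher and 511 lower in shPALI1.

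Because the pLKO libraries are shared, chance alone makes the fold changes of 2 knockdowns covary. Across genes, the covariance of log2 changes was 0.0556 for shPALI1 and shG9a, 0.0667 for shPALI1 and shsuz12 and 0.116 for shG9a and shsuz12. It was 0.0717 for shG9a and shJarid2 and 0.0878 for shJarid2 and shsuz12. Simulated unchanged groups gave 0.0123 to 0.0126, and 0 shared calls over 20 draws. For shPALI1 and shJarid2 the covariance was 0.00503, under the simulated 0.0126. The 3 controls cannot be split into sets of at least 2, so a part of the shared calls may come from them.

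In all 4 knockdowns, 267 genes rose and 459 fell, where 19.4 and 70.3 would be shared by independence. The count of rises was 473 with the length and GC correction, 405 with array weights and 402 with quantile normalization. That of falls was 768 with array weights and 261 without the genes that hold a word. Each knockdown group carried a hairpin, while pLKO carried a control vector. A response to any hairpin therefore cannot be told apart from one to loss of these factors, here and in the pairs. DYNLRB1 rose by 1.91 in shPALI1, 2.23 in shG9a, 2.63 in shJarid2 and 1.94 in shsuz12. CLU, whose product is a secreted chaperone, rose by 2.55, 2.41, 2.27 and 1.33 in the same order, and JUND, a component of the AP-1 transcription factor, by 1.36, 1.76, 1.86 and 1.16. CRISP3 rose by 0.64, 1.15, 2.50 and 2.34. S100P changed by -1.82, -1.54, -1.62 and -3.30, KLK3 by -1.89, -1.60, -0.86 and -0.90, and the mitotic activator gene CDC20 by -0.66, -1.01, -1.85 and -1.86. APLP1 changed by -1.44, -0.96, -1.83 and -0.91 and the cation transporter gene SLC22A3 by -1.10, -1.60, -0.88 and -1.36. Of these falling genes, SLC22A3 holds the words of shG9a and shsuz12, and KLK3 holds that of shJarid2.

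**Figure D3:**
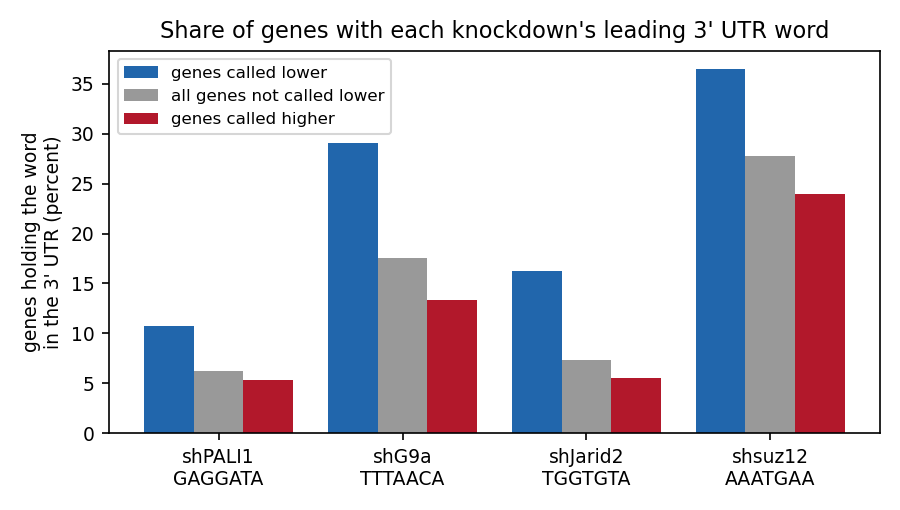
Percent of genes with an annotated 3′ UTR that hold the leading 7-base word of each knockdown, as bars for genes called lower, all genes not called lower and genes called higher. In each knockdown genes called lower hold the word most often, at 10.7% in shPALI1, 29.1% in shG9a, 16.3% in shJarid2 and 36.5% in shsuz12.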

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

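The tests of pairing between hairpin and 3′ UTR across genes, of the tie of the deviating shJarid2 library to length and GC content, of the share of reads from another group in it, of a wrong label and of the shared pLKO libraries were chosen after the results were seen. So were the alternatives that leave out word carriers or correct for length and GC content.

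Several named genes moved in opposite directions under a pair of knockdowns, with a limma test of the difference itself that passed. Between shPALI1 and shG9a, SCD differed by -3.90 (it fell by 2.46 and rose by 1.44) and PRAMEF12 by 3.72 (rose by 2.56, fell by 1.16). Between shPALI1 and shsuz12, CHRNA2 differed by -3.66 (-0.91 against 2.75), PRAMEF12 by 3.44 (2.56 against -0.88) and ACPP by -3.36 (-2.41 against 0.94). Between shPALI1 and shJarid2, KRT19 differed by -4.22 (-1.60 against 2.62) and ACPP by -3.82 (-2.41 against 1.41). These genes were picked because that test passed and both groups lay beyond all pLKO libraries, on opposite sides. All 3 libraries of one group therefore lay beyond the 3 of the other by the choice of genes, which adds no support. SCD holds the 3′ UTR word of shPALI1.

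In each knockdown the genes that fell shared a 3′ UTR word that may mark pairing with the seed of the hairpin: the t of the leading word across 10799 genes was -10.13 for GAGGATA in shPALI1, -20.14 for TTTAACA in shG9a, -16.34 for TGGTGTA in shJarid2 and -14.89 for AAATGAA in shsuz12, against -4.51, -5.01, -4.98 and -4.63 at the lowest in 100 shuffles and -1.24, -0.64, -3.58 and -2.14 at the lowest in the other knockdowns. Base composition of the 3′ UTR was argued against by anagrams of the word in shG9a, shJarid2 and shsuz12. Their lowest t was -7.4, -4.95 and -5.76. In shPALI1 an anagram that shares 5 bases in a row, TGAGGAA, reached -8.74. It also shares the run TGAGGA with TGAGGATA, the leading 8-base word of shPALI1. Its low t may therefore come from that word and cannot decide on base composition in shPALI1, which stays open. Genes with the word outside the 3′ UTR alone moved by -0.035, -0.023 and -0.076 in shPALI1, shG9a and shJarid2, against -0.153, -0.174 and -0.253 with it in the 3′ UTR, which argues against a word read anywhere in the transcript, while the -0.056 against -0.138 of shsuz12 leaves this open. The shG9a and shsuz12 values are what seed pairing would give. There the word extended by 1 base lies in 4 of 5 EHMT2 and 2 of 2 SUZ12 transcripts, outside their longest 3′ UTR. Of genes of similar length, 11.4% and 27.1% hold it. Genes with several copies fell further (-0.263 against -0.142 and -0.22 against -0.089). Seed pairing cannot be told apart in shPALI1. There 5 of 6 LCOR transcripts hold the extended word, but copies added little (-0.163 ± 0.06 against -0.153). In shJarid2 copies added to the fall (-0.363 ± 0.051 against -0.238 ± 0.017). The extended word lies in 0 of 2 JARID2 transcripts. Hairpin sequences were not given, so the added base may lie outside a seed, and this absence does not argue against pairing. The 7-base word lies in 2 of 2 JARID2 transcripts, and 21.3% of genes of similar length hold it. It was looked up only afterwards, so seed pairing stays open in shJarid2. With 1 hairpin name per target, loss of the target remains an open biological explanation for any carrier gene, and word carriers were 318 of 2965, 835 of 2871, 491 of 3020 and 1402 of 3845 of the genes that fell and 19, 54, 42 and 64 of the 100 largest falls in shPALI1, shG9a, shJarid2 and shsuz12, so pairing is a weightier concern for the largest falls than for the rest.

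The third shJarid2 library stood apart from the other two of its group, with an SD of its deviation across genes of 0.385, against 0.276 and 0.234 for its replicates and 0.242 at the highest in the other groups. Correction for transcript length and GC content lowered the SD to 0.294, still above the 0.233 and 0.212 of its replicates and the 0.231 at the highest in the other groups, so this trend does not account for the whole. A wrong label is argued against by its JARID2 level of 1.32 RPKM, below the 1.7 and 1.72 RPKM of its replicates. A share of 0.1 or more of reads from shPALI1, shG9a or shsuz12 is argued against by genes at least 4-fold higher there, whose median shares of 0.018, 0.014 and 0.012 had 95% bootstrap intervals up to 0.046, 0.039 and 0.049. A part may come from length or GC content. The Spearman rho of its deviation across genes was -0.6 with transcript length and 0.47 with GC content. In libraries of the other groups, rho reached -0.38 with length (shPALI1 replicate 1) and 0.65 with GC content (pLKO replicate 1). A part may also come from pLKO reads (slope 0.115, median share 0.05 with an interval from -0.005 to 0.11). These explanations cannot be told apart, although 12 of 33 such genes and JARID2 lie below the replicates. No biological explanation was tested, since the labels give none within the group.

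Cholesterol synthesis genes fell under shPALI1 and rose under shG9a, a median log2 difference of -1.194 with 18 of 19 members lower; this is the difference of the changes already seen, so an effect of the shared pLKO libraries on the fall or on the rise cannot be told apart. Without the carriers of the shPALI1 word, the median in shPALI1 was -0.42 over 17 of 19 genes, so the fall does not rest on these carriers alone. Whether this word marks the seed of the hairpin was left open above. Direct pairing of the other members through another sequence was therefore not tested. Transcript length and GC content were argued against by a median difference of -1.113 after correction, with 18 members lower. A biological explanation, that PALI1 and G9a may act in opposite ways on this pathway, stays open as a hypothesis. So does an indirect route, since SREBF2, a regulator of the pathway, and SQLE hold the shPALI1 word and a fall in SREBF2 could lower the other members; this route was not tested.

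For each count of genes called, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups, so a difference between the groups widens its spread and lowers its calls. The counts of the other splits therefore do not measure how many calls chance gives. The real count and the highest of the other splits were 5290 and 1 for shPALI1, 5477 and 2 for shG9a, 6486 and 1 for shJarid2 and 6854 and 0 for shsuz12 against pLKO. They were 6127 and 0 for shPALI1 against shG9a, 7113 and 1 against shsuz12, 7921 and 1 against shJarid2, and 7499 and 0 for shsuz12 against shJarid2.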

How the results depend on the processing

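Alternatives added after seeing the data were those without word carriers, with the length and GC correction, and the list tests that leave out a library. For named genes, leaving out 1 library kept direction and side of the threshold in 3108 cases, ended the call in 77 and added it in 13, and pseudocounts of 0.1 and 0.5 kept 528 and 532. ENO2 in shJarid2 reversed with array weights (-0.353, adjusted p = 0.0252, against 0.03); their estimation stopped before it converged, and the cause was not tested. Without word carriers, where fewer genes were tested, genes lower were 2750 in shsuz12 and 2832 in shsuz12 against shJarid2, genes higher in shPALI1 against shsuz12 were 2485, and falls shared by shsuz12 were 1006 with shPALI1, 1178 with shG9a, 1046 with shJarid2 and 261 in all 4. With the length and GC correction, rises shared by shPALI1 were 1325 with shG9a, 1022 with shJarid2 and 1475 with shsuz12, and 473 genes rose in all 4. Array weights gave falls shared by shJarid2 of 1552 with shPALI1 and 2054 with shG9a, with 405 rises and 768 falls in all 4. TPM gave 1248 falls shared by shG9a and shsuz12, and quantile normalization 402 rises in all 4. Counts of genes called per comparison, and of genes called in the same direction in 2 or in all 4 knockdowns, kept within 1.5 times under the other alternatives. The counts of 2-fold changes, of opposite calls and of genes without overlap were not among those compared. Lists called higher and lower were 4 and 6 in shPALI1, 1 and 3 in shG9a, 1 and 3 in shJarid2 and 2 and 3 in shsuz12. With an estimated correlation they were 2 and 2, 1 and 1, 0 and 0, and 0 and 0. With fry, which does not compare a list with other genes, lists called higher were 8, 9, 5 and 6, and lists called lower were 11 in shG9a, 8 in shJarid2 and 7 in shsuz12. In shG9a, lists called higher were 2 with median ratio scaling, with the length and GC correction and without word carriers, and 1 to 3 over leaving out a library (3 without shG9a replicate 1). Lists called lower in shG9a were 3 to 5 (5 without pLKO replicate 3), and without word carriers lists called higher in shsuz12 were 1. Apart from the word carriers, the cause was not tested. With the replicate number as a term, 38 of 38 counts stayed within 1.5 times and 528 named genes kept their call; deviations of libraries with the same number correlated between -0.27 and 0.3, and 7 of 15 libraries matched best with their own number. Depth limits genes near 1 RPKM, which rest on 21.1 to 38.7 reads in a gene of 2 kb.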

Other observations

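The gene lists below were written after the largest changes had been seen, and the ribosomal list after 2 of its members had been seen, and the stricter tests without such genes were chosen after the first results. Because the lists were built around genes that had led the comparison, and because a filter at 1 RPKM favours genes that rise from low levels, each list was tested again with no filter and without the members seen or named before. The record of genes seen before was corrected after a first result of this stricter test was known. Many cleavage-stage and UGT2B genes have near-identical copies, so how their reads divide among copies is uncertain, and the counts overstate the number of independent genes where copies share reads.

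Genes of the cleavage-stage embryo were higher under shPALI1, and the values do not separate an effect of PALI1 from one of the hairpin. Of 18 tested members, 17 rose (camera adjusted p = 8.2e-21, 0.0015 with an estimated correlation), and without the 4 genes seen before, 19 of 25 rose and 0 fell (median log2 change 1.13, adjusted p = 4.6e-24, 1.5e-05 with an estimated correlation). ZSCAN4, one of the genes seen before, rose from 0.125 to 4.92 RPKM (log2 change 2.39). TRIM48 rose by 2.21 and CCNA1 by 1.71. Under each of the other knockdowns 0 of the 18 rose and 2 fell; of the 25, 0 rose and 1 fell in shG9a and in shJarid2, and 1 rose and 1 fell in shsuz12.

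A list of actin cytoskeleton genes and targets of the actin-regulated factors YAP and SRF rose under shPALI1, 14 of 18 against 1 that fell (adjusted p = 4.4e-13, 0.0015 with an estimated correlation). Without the 5 genes seen before, 10 rose against 1 of 15 that fell (adjusted p = 2.4e-08, 0.0023 with an estimated correlation). Of the 18, the gene that fell was TAGLN (log2 change -0.55, limma adjusted p = 0.00056), and TPM1 (0.14), TPM2 (-0.09) and VCL (0.13) did not pass. CYR61 rose from 2.59 to 15.5 RPKM, FLNA, which encodes filamin, from 62.1 to 216 RPKM and CNN2 by a log2 change of 1.77. The full list also moved up in shG9a (13 against 1) and shsuz12 (12 against 2), with adjusted p = 0.00022 and 9.8e-05, and 0.063 and 0.085 with an estimated correlation. In shJarid2 the list did not pass (6 higher, 5 lower, adjusted p = 0.6). The values do not separate an effect of PALI1 from one of the hairpin.

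Fatty acid synthesis genes fell under shPALI1, 11 of 13 against 1 that rose (adjusted p = 1.5e-05, 0.014 with an estimated correlation), and 10 of 11 without the genes seen before (median -0.72, adjusted p = 5.5e-07, 0.0041 with an estimated correlation). FASN, which encodes the synthase, fell from 313 to 200 RPKM under shPALI1 and rose to 670 RPKM under shG9a. FADS2 changed by -0.96 and 1.23 in the same pair. SREBF1, the regulator of these genes, fell by 1.05 under shPALI1. In shG9a the full list passed with the preset correlation (adjusted p = 0.032) but not with an estimated correlation (0.24) or without the genes seen before (0.14). The fall under shPALI1 may share its cause with that of the cholesterol genes; this was not tested.

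A list for the conjugation of steroids with glucuronic acid held UGT2B genes and UGDH, which is not a UGT2B gene. It rose under shPALI1, 7 of 7 (adjusted p = 3.9e-08, 0.0056 with an estimated correlation). Without the genes seen before, 4 of 4 rose (adjusted p = 1.7e-06, 0.0023 with an estimated correlation). Under shG9a 6 of 7 rose (adjusted p = 5.2e-08, 0.014 with an estimated correlation), and UGDH did not pass (log2 change 0.14, limma adjusted p = 0.1). UGT2B11 rose by 1.78 under shPALI1. UGT2B15 and UGT2B17 are genes that androgen receptor activity lowers in LNCaP cells. UGT2B15 rose by 1.88 and UGT2B17 by 0.37 under shPALI1, where the androgen receptor list fell. They rose by 2.65 and 2.02 under shG9a and by 1.23 and 0.98 under shJarid2, where that list had adjusted p = 0.17 and 0.96, and by 0.85 and 0.50 under shsuz12, where it had 0.27. In shJarid2 UGT2B11 fell by 0.85 and UGT2B28 fell by 1.56, and the glucuronidation list did not pass (adjusted p = 0.54). A link between these changes was not tested.

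Cytosolic ribosomal protein genes had adjusted p = 1.5e-05 in shPALI1, with 9 of 33 higher, but adjusted p = 0.37 with an estimated correlation, and 0.00011 and 0.41 without the genes seen before. In shG9a 0 rose and 10 fell (adjusted p = 0.0086, 0.6 with an estimated correlation) and in shJarid2 0 rose and 13 fell (0.0017 and 0.74). Without the filter and the genes seen before, 5 of 31 rose in shPALI1, 1 fell in shG9a and 9 fell in shJarid2. Whether they move as a group was left open by the gap between these values.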
